A study of Mus musculus with 2 samples.

How the data were processed

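MicroRNA sequencing was performed on limb tissue of mouse embryos at 12.5 days of development. Per the labels, the tissue came from the strain B6NCrl, embryos of both sexes were pooled, and the sequenced RNA was the fraction of total RNA shorter than 30 nucleotides. The labels place both libraries in 1 group and number them as biological replicates 1 and 2, from pools of 88 and 68 embryos. With 1 group there is no contrast between conditions, so the design implies a description of microRNA levels, of the spread between the replicates and of fixed sets of microRNA genes.

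The deposited tables hold whole-number read counts per microRNA gene, one row per gene. Per the README deposited with each library, reads were placed on the mouse assembly mm10 and counted over the genes of GENCODE release M4. The aligner, the counting program and their versions are not given in the sources used here, nor are adapter trimming and mismatch settings. Each table has no header line and holds 3 count columns. In all genes the first column equalled the sum of the other two, which were read as the gene's own strand and the opposite strand. The counts of the gene's own strand were used. The tables also hold 4 rows that name no gene, for unmapped reads, reads that mapped to several places, reads outside the annotated genes and ambiguous reads. Because the deposited count tables set apart reads that map to several places, microRNAs made from more than 1 genomic copy with the same mature sequence could lose most of their reads. Each count covers a whole hairpin, so the 5' and 3' arms were not separated.

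Replicate 1 was the deeper library. Replicate 1 held 10646293 reads, of which 4525636 (42.5%) were counts on microRNA genes, and replicate 2 held 9738708 reads, of which 3604284 (37.0%) were. The rows that name no gene were left out of all totals. In replicate 1 they held 23.8% of the reads as unmapped, 27.2% as mapping to several places and 6.49% outside the annotated genes, against 32.6%, 23.7% and 6.70% in replicate 2, with 0 ambiguous reads in either. Since the gene's own strand was counted, the reads outside the genes include those on the opposite strand of a gene. A count of 0 allowed up to 3 counts, which is 0.663 CPM (counts per 1000000 gene counts) in replicate 1 and 0.832 in replicate 2. Shares of single libraries carry 95% Clopper-Pearson intervals. These intervals and floors cover counting error only, since reads amplified by PCR are not independent molecules.

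Gene identifiers were matched without their version number to GENCODE M21, which annotates GRCm38, the assembly also called mm10. Of 1973 gene rows 1894 matched, and the 79 that did not match held 1 count in replicate 1 and 2 counts in replicate 2. Symbols, coordinates, host genes and hairpin sequences came from this annotation. Of the matched genes, 929 had a hairpin that shared a stretch of 20 nucleotides or more with the hairpin of another microRNA gene elsewhere in the genome, and any such gene is named with that limit. Hairpins that overlap each other, as on opposite strands, were not compared. The reference held 308 microRNA genes that have no row in the tables, and 32 rows overlapped such a gene on the other strand.

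Levels were expressed as CPM and given as the mean ± SD over the 2 replicates. A gene was called detected at 10 CPM or more in both libraries. Agreement was measured across genes by Pearson and Spearman correlation of log2(CPM + 1) for genes at 1 CPM or more in the mean. Genes are not independent replicates, so no p-value is attached. The biological coefficient of variation was the square root of the common dispersion from edgeR 4.0.16 (R 4.3.3) with trimmed-mean scaling and an intercept-only design, over genes with 10 counts or more in the sum, with an interval from 100 resamplings of genes. Genes were compared between the 2 libraries with a two-sided exact binomial test on their counts, conditional on the sum, with Benjamini-Hochberg adjustment and a threshold of 0.05. That test compares these 2 libraries with counting error alone, not conditions. Log2 ratios are replicate 2 over replicate 1, with 0.5 counts added to each library, and their standard errors (SE) cover counting error.

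Before the data were examined, 20 sets of microRNA genes were fixed. They covered the Hox clusters, muscle, cartilage, mesenchyme, smooth muscle and pericytes, epithelium, endothelium, red blood cell precursors, white blood cells, neural tissue, sensory cells, a set of liver, gut and pancreas, pluripotent cells, the let-7 family, the miR-17-92 cluster with its paralogs, the Dlk1-Dio3 region, the Mir322-Mir503 region, Igf2 and H19, the Mir297, Mir466, Mir467 and Mir669 families, taken by name, and an X-linked testis cluster. Members were matched by symbol, and 4 by a synonym in the RefSeq table of GRCm38. The level of each set was given as a share of the counts, and the median log2(CPM + 1) of its members was placed as a percentile among 10000 random sets of the same size. The difference of a set between the libraries was the median log2 ratio of its members at 10 CPM or more, placed among 10000 random sets matched on mean expression by drawing each member from its 30 nearest genes by level. The genes named were fixed by a rule set at the same time. It took the 20 genes with the highest mean CPM, up to 4 members per set with the highest mean CPM, any member of a tissue set at 100 CPM or more in both libraries, and, among genes at 100 CPM or more in the mean, the 5 with the most extreme log2 ratio toward each replicate with an adjusted p under 0.05. Genes named for 0 or few counts, cluster neighbours and Mir7j were chosen after their values were seen.

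The procedures were tested on simulated counts drawn from the real gene levels and library sizes. With counting error alone and 200 genes changed, of which 66, 62 and 62 were among the 436 tested at changes of 1.2, 1.5 and 2 times, the binomial test called 56.1%, 72.6% and 85.5% of them. It called 10.2% of the unchanged genes with the estimated scaling and 0.813% with the true scaling, since at high counts a small scaling error passes a test of counting error. With a coefficient of variation set to 20% and no changed gene, the estimate was 19.7% over 432 genes, and the binomial test called 45.8% of them. The alternative, a negative binomial exact test that takes its dispersion from the same 2 libraries, made 0 calls in all 5 simulations, including those with 200 changed genes, so its count is no evidence that levels were equal. For random sets of 10 genes drawn from 298, 6% of 400 sets without a shift lay outside the central 95%, and 73.5% did when shifted by 0.3 on the log2 scale, the SD of the simulated ratios. The tissue sets tested for a shift had only 2 to 9 members at 10 CPM or more. Smaller sets and sets of cluster neighbours were not simulated, so the 73.5% does not hold for them.

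Alternatives covered detection at 1 and 100 CPM, scaling by library totals or by the size factors of DESeq2 1.42.0, other pseudocounts (0.5 and 10 CPM) and count minimums, the counts of both strands, sets without the most abundant gene or without members that share a stretch, and each replicate left out in turn. Further alternatives were added after the data were seen. Statistics were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9. Signal tracks of the libraries were not analysed here.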

Results

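The microRNA content of the mouse limb at embryonic day 12.5 was measured by small RNA sequencing in 2 pools of limbs. At this stage the limb holds condensing cartilage, muscle precursors and a covering ectoderm. Replicate 1 pooled limbs of 88 embryos and gave 4525636 counts on microRNA genes, and replicate 2 pooled limbs of 68 embryos and gave 3604284. All values are means ± SD over these 2 replicates (n = 2) unless a library is named, and coordinates are those of mm10. The question the design addresses is which microRNA genes gave reads in the limb at this stage and at what level. How well each microRNA sequence was recovered was not measured, so levels compare read counts between genes, not molecules.

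Mir196b, Mir335, Mir322, Mir214 and Mir17 led the profile. By reads that could be assigned, Mir196b was the most abundant gene at 86831 ± 9376 CPM, or 8.68% ± 0.94 of the counts. It lies in the HoxA cluster (chromosome 6, 52230081 to 52230165, minus strand, overlapping an exon of an annotated Hoxa9 transcript). Mir335, in an intron of the imprinted gene Mest (chromosome 6, 30741299 to 30741396, plus strand), followed at 76218 ± 6236 CPM. The X-linked Mir322 (53054255 to 53054349, minus strand), with no host gene on its own strand, came next at 68344 ± 659 CPM. Mir214, in an exon of the long non-coding RNA Dnm3os (chromosome 1, 162223368 to 162223477, plus strand), stood at 51056 ± 7523 CPM, and Mir17, in an exon of Mir17hg (chromosome 14, 115043671 to 115043754, plus strand), at 50945 ± 7438 CPM. The order of Mir214 and Mir17 was not resolved, since replicate 1 placed Mir17 higher and replicate 2 placed Mir214 higher.

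The next genes were Mir99a at 37341 ± 1902 CPM, Mir23b at 36314 ± 9350, Mir99b at 30885 ± 3617, Mir130a at 27130 ± 477 and Mir140, the cartilage microRNA, at 23899 ± 1020. Mir26b, Mirlet7g, Mir30e, Mir10b, Mir126a, Mirlet7i, Mir20a, Mir93, Mir23a and Mir100 completed the 20 highest genes, from 23448 ± 1113 CPM for Mir26b down to 11442 ± 34 CPM for Mir100. Mir23a (13747 ± 3537 CPM) and Mir23b share a stretch with each other, so reads common to both could not be assigned, and both values are uncertain. The 10 highest genes held 48.9% ± 0.66 of the counts and the 20 highest 67.2% ± 1.12. In all, 286 genes were detected at 10 CPM or more in both libraries and held 99.9% of the counts, 189 reached 100 CPM in the mean, 93 reached 1000 CPM and 23 reached 10000 CPM. No count fell on 1256 of the 1973 genes in either library. The number detected depended on the threshold and was 186 at 100 CPM in both libraries. Reads that mapped to several places, 27.2% in replicate 1 and 23.7% in replicate 2, are left out of these ranks, shares and numbers. MicroRNAs with identical copies could therefore stand higher than shown here.

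**Figure D1:**
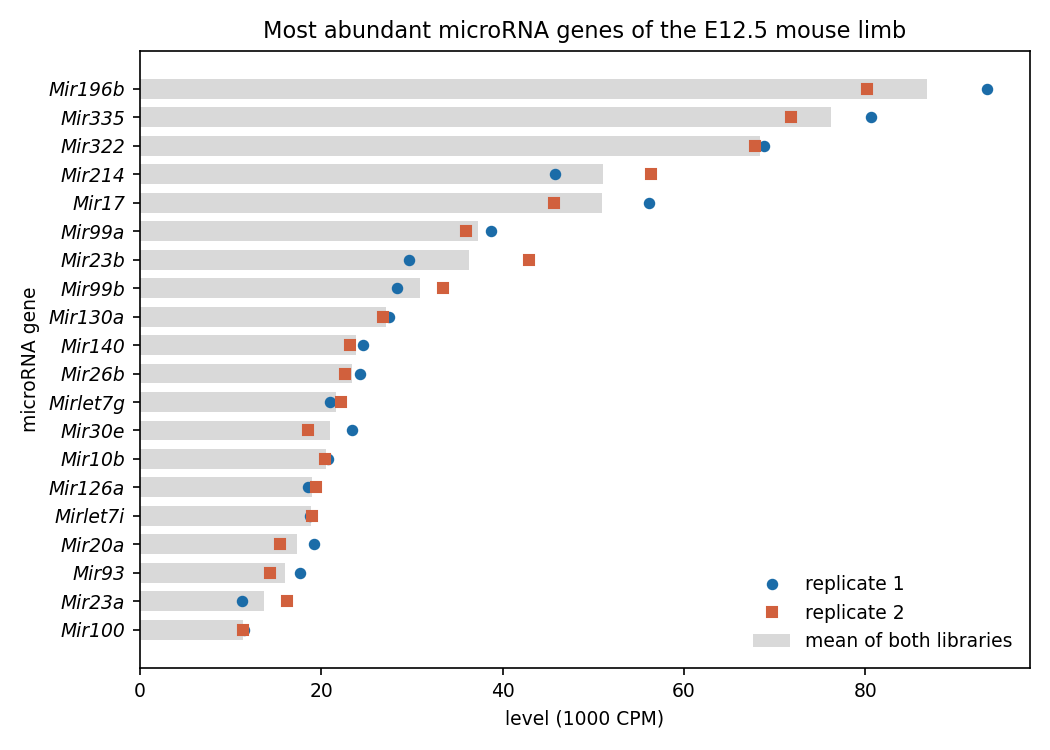
Levels of the 20 most abundant microRNA genes in units of 1000 CPM, with grey bars for the mean of both libraries and a point for each replicate. Mir196b, Mir335 and Mir322 lay above all others in both replicates, and the points of Mir196b and Mir23b stood furthest apart.

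Among the genes of the Hox clusters, which pattern the limb along its axes, all 6 measured members were detected, and together they held 12.0% ± 0.94 of the counts. Mir196b made up 72.4% of this share and exceeded the next member, Mir10b in an intron of Hoxd3 (chromosome 2, 74726070 to 74726137), by 4.51 times in replicate 1 and 3.93 times in replicate 2. Mir10b stood at 20574 ± 218 CPM, Mir10a of the HoxB cluster at 7497 ± 559 CPM and Mir615 of the HoxC cluster at 3302 ± 722 CPM. The genomic copies Mir196a-2 (1678 ± 28 CPM) and Mir196a-1 (31.4 ± 2.3 CPM) share a stretch with another gene, so their levels are uncertain. The part of Mir196b in the set holds only for reads that could be assigned.

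Sets of the limb's own tissues were all present at different levels. The cartilage set held 2.56% ± 0.058 of the counts, of which Mir140, in an exon of a transcript of Wwp2 (chromosome 8, 107551244 to 107551313, plus strand), made up 93.3%, with Mir455 in an intron of the collagen gene Col27a1 at 1713 ± 442 CPM. The mesenchyme set held 5.36% ± 0.72, of which Mir214 made up 95.3%. Its other members Mir199b (1917 ± 192 CPM), Mir199a-2 (551 ± 141 CPM) and Mir199a-1 (30.6 ± 2.4 CPM) each share a stretch with another gene. The mesenchyme share and the part of Mir214 in it hold only for reads that could be assigned. The muscle set held 0.248% ± 0.020, and 94.8% of it came from Mir206, a microRNA of skeletal muscle (chromosome 1, 20679010 to 20679082, plus strand), at 2347 ± 213 CPM. Mir208b and Mir499, in introns of the myosin genes Myh7 and Myh7b, stood at 45.3 ± 1.6 and 25.2 ± 6.9 CPM, and Mir133b, which shares a stretch with its copies, at 45.1 ± 2.5 CPM. Of the 10 measured muscle genes, 4 were detected. Both Mir133a copies had 0 counts in both libraries and Mir1a-1 had 11 counts in replicate 1 and 0 in replicate 2. All 3 have near-identical copies, so the muscle share is a lower limit.

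The epithelium set, which in the limb marks the ectoderm, was detected in all 7 members and held 1.88% ± 0.027 of the counts. Mir205 led it at 7403 ± 120 CPM, followed by Mir203 at 4587 ± 119, Mir429 at 3712 ± 152 and Mir200c at 1585 ± 139 CPM. Mir200b (982 ± 1.7 CPM), Mir200a (313 ± 24 CPM) and Mir141 (196 ± 42 CPM) completed it. The endothelium set rested on 1 measured gene, Mir126a in an exon of a transcript of Egfl7 (chromosome 2, 26591357 to 26591429), at 18968 ± 624 CPM. For smooth muscle and pericytes, Mir143 stood at 5260 ± 26 CPM and exceeded Mir145a (75 ± 5.2 CPM), which lies beside it on the same strand of chromosome 18, by 66.6 times in replicate 1 and 74.0 times in replicate 2.

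Among the sets of other tissues and of blood, sensory cells reached 0.633% ± 0.012, and the rest held lower shares. The sensory share lay above the muscle and the smooth muscle and pericyte sets. The order against muscle holds only for reads that could be assigned, since the muscle share is a lower limit and no sensory member shares a stretch. The red blood cell set held 0.0257% (95% interval 0.0242 to 0.0272) in replicate 1 and 0.0180% (0.0166 to 0.0194) in replicate 2, led by Mir451a at 174 ± 54 CPM, with Mir486 at 22.6 ± 7.3 and Mir144 at 21.9 ± 7.4 CPM. Mir451a and Mir486 overlap Mir451b and Mir3107 on the other strand, set members without a row. Whether reads common to such a pair were left unassigned was not tested, so these levels and the share are uncertain. The white blood cell set held 0.0671% ± 0.0077, from Mir155 (338 ± 1.1 CPM), Mir223 (275 ± 52 CPM) and Mir146 (52.7 ± 24.8 CPM, with a shared stretch), with Mir150 at 4.32 ± 1.74 CPM. Its member Mir142 was not among the measured genes, but 349 ± 25 CPM lay opposite to Mir142b, which overlaps it. With these counts added, an alternative chosen after the data were seen, the set held 0.102%. The neural set held 0.0713% ± 0.0064, and its highest members were Mir128-1 (157 ± 46 CPM, with a copy), Mir137 (151 ± 9.9 CPM), Mir128-2 (85.5 ± 40.0 CPM, with a copy) and Mir132 (77.8 ± 0.64 CPM). The neural microRNA genes Mir124a-1, Mir124a-2, Mir124a-3 and Mir9-2 had 0 counts in both libraries, but 11 of the 15 measured members share a stretch, so this set is also a lower limit. Without them it held 0.0269%. In the sensory cell set all 3 members were detected, with Mir182 at 3011 ± 505, Mir183 at 2472 ± 484 and Mir96 at 842 ± 104 CPM. In the set of liver, gut and pancreas 91.8% of the share of 0.165% ± 0.015 came from Mir375, an islet and endocrine cell microRNA, at 1511 ± 143 CPM. The gut microRNAs Mir192 (67.2 ± 6.2 CPM) and Mir194-2 (43.7 ± 2.9 CPM, with a copy) and the liver microRNA Mir122 (15.0 ± 2.8 CPM) followed. The set of pluripotent cells held 0.0362% ± 0.000053, with Mir302a at 124 ± 5.4, Mir302d at 105 ± 11, Mir302b at 94.2 ± 10.8 and Mir302c at 15.1 ± 3.0 CPM, of which Mir302a and Mir302b share a stretch. Without the 4 members that share a stretch this set held 0.0143%.

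**Figure D2:**
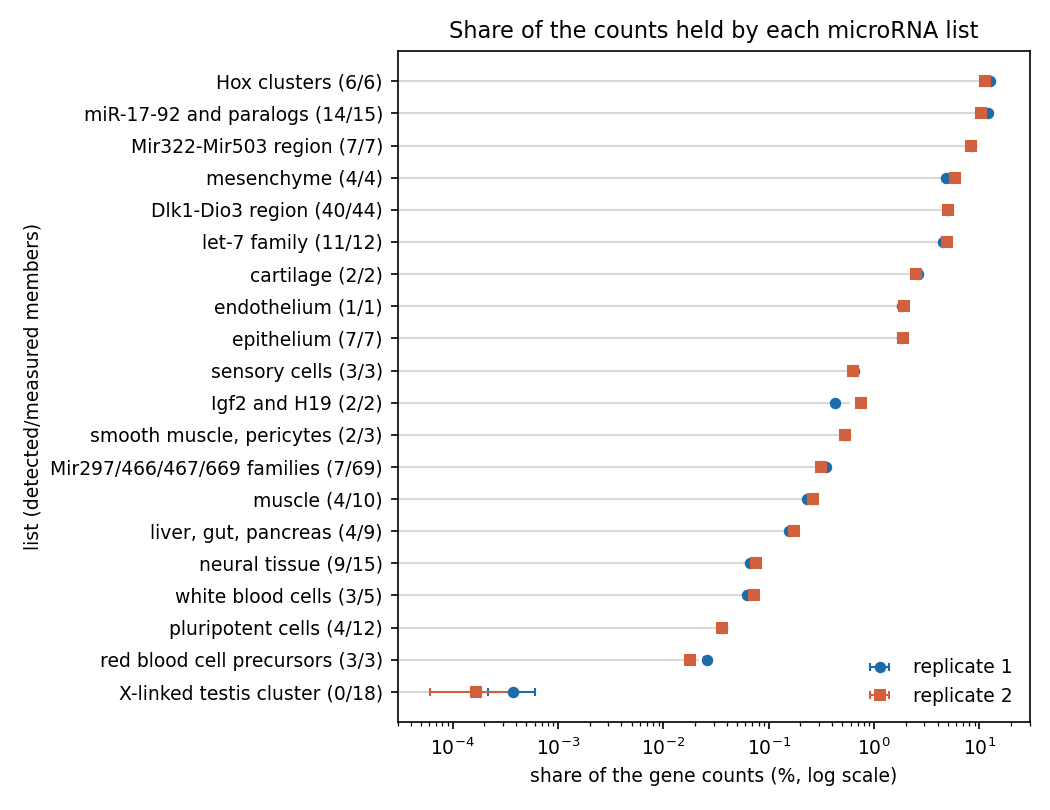
Share of the gene counts held by each fixed set of microRNA genes in replicates 1 and 2, in per cent on a log scale, with 95% Clopper-Pearson intervals as bars that are mostly narrower than the points and the detected and measured members in brackets. The Hox, miR-17-92 and Mir322-Mir503 sets lay highest, and the X-linked testis cluster lay below all others.

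Several clusters and the imprinted Dlk1-Dio3 region held large shares. The miR-17-92 cluster and its paralogs, known for their levels in proliferating cells, held 11.2% ± 1.25 of the counts with 14 of 15 members detected. Mir17 made up 45.6% of it, followed by Mir20a (17376 ± 2636 CPM), Mir93 (16019 ± 2327 CPM) and Mir106b (10448 ± 458 CPM). Of the 15 measured genes 4 share a stretch, so this share and the part of Mir17 hold only for reads that could be assigned. The X-linked Mir322-Mir503 region held 8.33% ± 0.0049, with Mir351 at 10746 ± 917, Mir503 at 2598 ± 156 and Mir542 at 1234 ± 33 CPM beside Mir322. In the imprinted Dlk1-Dio3 region of chromosome 12, which carries a maternally expressed microRNA cluster, 40 of 44 measured genes were detected. They held 5.03% ± 0.022 and were led by Mir487b (6482 ± 156 CPM) and Mir411 (5993 ± 94 CPM), both with a shared stretch, Mir431 (5391 ± 103 CPM) and Mir127 (5023 ± 200 CPM), and without the 4 members that share a stretch the region held 3.75%. A further 6 members of the set, among them Mir409, had no row. Opposite to Gm24321, which overlaps Mir409, lay 6605 ± 434 CPM, above Mir487b, so the order holds only for genes with a row. With other-strand counts of such members added, an alternative chosen after the data were seen, the region held 6.03%. The let-7 family held 4.71% ± 0.23, mostly from Mirlet7g (21638 ± 861 CPM) and Mirlet7i (18881 ± 138 CPM), with Mirlet7d at 3598 ± 1159 and Mir98 at 1876 ± 81 CPM. Of its 12 measured genes 5 share a stretch, among them Mirlet7f-2 at 411 ± 13 and Mirlet7c-2 at 13.4 ± 2.7 CPM, and Mirlet7e and Mirlet7f-1 were not among the measured genes. The share is therefore a lower limit, and the lead of Mirlet7g and Mirlet7i holds only for reads that could be assigned. The Igf2 and H19 set held a smaller share, 0.588% ± 0.227. Its member Mir483 stood at 5718 ± 2314 CPM and Mir675, in an exon of H19, at 159 ± 42 CPM. The Mir297, Mir466, Mir467 and Mir669 families, of which 59 of 69 measured genes lie in an intron of Sfmbt2 on chromosome 2, held 0.330% ± 0.023. The 10 genes elsewhere had 0 counts. In all 67 of the 69 share a stretch and 7 were detected, so the highest values, Mir467d at 1030 ± 26, Mir467e at 842 ± 38, Mir467c at 773 ± 62 and Mir669l at 271 ± 43 CPM, are uncertain, and without the 67 the share was 0.000011%. No member of the X-linked testis cluster was detected: its 18 genes held 17 counts in replicate 1 and 6 in replicate 2, and Mir741 was highest at 1.36 ± 0.04 CPM.

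Beside random sets of the same size, 18 of the 20 sets had a median level at or above the 95th percentile. The others were the Mir297, Mir466, Mir467 and Mir669 families at the 49.6th percentile and the X-linked testis cluster at the 41.8th. Most annotated microRNA genes had 0 counts, so this comparison sets the bar low.

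The replicates ranked genes alike and differed by more than counting error. Across 452 genes at 1 CPM or more, Pearson's r was 0.993 (95% interval 0.992 to 0.995) and Spearman's rho was 0.985 (correlations across genes, which are not independent replicates). The biological coefficient of variation was 16.3% (interval 14.6 to 17.8) over 436 genes. This interval comes from resampling genes within the same libraries, so it does not cover the spread over further pools of embryos. Of the 189 genes at 100 CPM or more, 173 lay within 1.5 times between the libraries, 16 lay outside and 1 differed by over 2 times. The log2 ratios of these genes had an SD of 0.32 against a median counting SE of 0.033. A chi-square of 64066 on 435 degrees of freedom, which treats reads as independent molecules, showed that the tables differ by more than counting error alone. That they are separate samples rests on the labels.

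Genes above in replicate 2 were led by Mir92b, with a log2 ratio of 1.02 (SE 0.037) and a level of 820 ± 401 CPM. Mir505 (0.86), Mir493 (0.85), Mir483 (0.83) and Mir181a-2 (0.80, with a copy) followed. Genes above in replicate 1 were led by Mir350 with -0.67 (SE 0.061) and Mir451a with -0.67 (SE 0.080), followed by Mir181b-2 (-0.64, with a copy), Mir667 (-0.63) and Mir362 (-0.61). The exact binomial test, with counting error alone, called 178 of 436 genes at a Benjamini-Hochberg adjusted p under 0.05, of which 81 were higher in replicate 2 and 97 in replicate 1. Mir362 had an adjusted p of 1.47e-12 in this test, the largest among these 10 genes. A negative binomial exact test in edgeR with the dispersion of the same replicates called 0 genes, with 26 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0863.

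**Figure D3:**
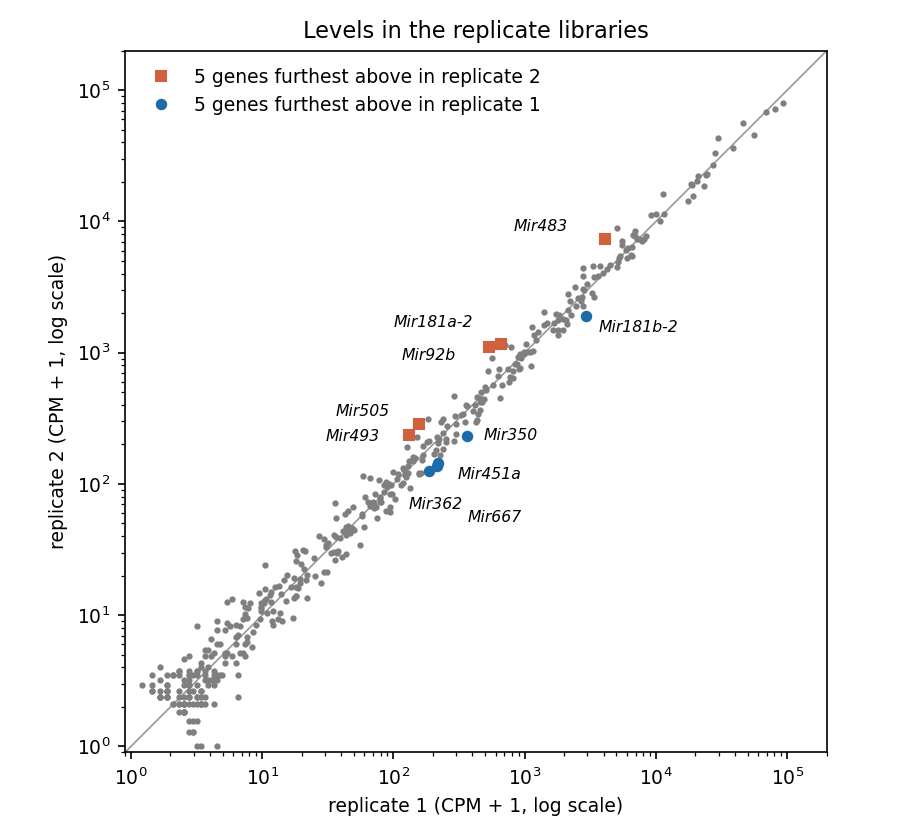
Level of each microRNA gene in replicate 1 (horizontal) and replicate 2 (vertical), as CPM plus 1 on log axes, for genes at 1 CPM or more in the mean, with a line of equality. Coloured points mark the 5 genes furthest above in each replicate by the fixed rule, which reach a log2 ratio of 1.02 for Mir92b and -0.67 for Mir350.

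Of 18 sets with 2 or more members at 10 CPM, the red blood cell set alone lay outside the central 95% of matched random sets between the libraries, where chance gives 0.9 set. Its median log2 ratio was -0.67, at the 0.19th percentile (central 95% from -0.52 to 0.62), as Mir451a and Mir144 were lower in replicate 2 (log2 ratios of -0.67 and -0.72) while Mir486 was higher (0.65). Mir451a and Mir144 are neighbours on chromosome 11, so they are not independent members. Mir451a and Mir486 each overlap a gene on the other strand, and loss of reads shared with it was not tested. All 3 members were called by the binomial test, over all genes and adjusted over the list alone, and 0 by the negative binomial test either way. The white blood cell set had a median of 0.37 at the 96.0th percentile, and with members from 1 CPM it moved to 0.59 at the 99.6th. The let-7 family had a median of 0.08 at the 90.9th percentile with Mir7j, a member matched by synonym, and 0.23 at the 99.6th without such members. In the other sets the binomial calls over all genes and adjusted over the list alone were equal in number, except for epithelium with 5 and 6 of 7 members. The negative binomial test called 0 members of any set over all genes. Adjusted over the list alone, it called 1 in muscle (Mir1a-1), 1 in white blood cells (Mir146), 2 in pluripotent cells (Mir292 and Mir294) and 1 for Igf2 and H19 (Mir483). Of these, Mir1a-1, Mir292 and Mir294 were below the detection threshold, and Mir1a-1 and Mir146 share a stretch. No adjustment was made across sets.

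On the strand opposite to the annotated gene lay 2.39% (95% interval 2.37 to 2.40) of the counts of both strands in replicate 1 and 2.62% (2.60 to 2.63) in replicate 2. Without rows that overlap a microRNA gene on the other strand, the mean share was 0.0043%.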

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

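The tests of opposite-strand counts were chosen after those counts were seen. The main measurement used the gene's own strand, and 18 rows carried more counts on the opposite strand, in both libraries, than a count of 0 allows. The highest were 5 rows named Gm genes. Opposite-strand levels stood at 6605 ± 434 CPM for Gm24321, which overlaps Mir409 of the Dlk1-Dio3 region (chromosome 12, 109743158 to 109743237), 6111 ± 1259 CPM for Gm25927, which overlaps Mirlet7e (chromosome 17, 17830343 to 17830459), and 5331 ± 82 CPM for Gm25301, which overlaps Mir378a (chromosome 18, 61397813 to 61397925). Gm24083, over Mir191, held 2327 ± 313 CPM and Gm25252, over Mir376a, 1618 ± 256 CPM. On their own strand these 5 rows had 0 counts. As genes of their own, the first 3 would take ranks 33, 36 and 43.

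Lower opposite-strand levels were 1352 ± 104 CPM for Mir299b (over Mir299a), 1073 ± 210 for Gm25750 (over Mir380), 659 ± 19 for Mir497b (over Mir497), 349 ± 25 for Mir142b (over Mir142), 148 ± 23 for Mir3074-1 (over Mir24-1) and 27.6 ± 7.2 for Gm24111 (over Mirlet7f-1). Mir203 held 19.96 ± 1.98 CPM, Mir708 6.67 ± 1.19, Mir126a 3.76 ± 2.18, Mir486 2.79 ± 1.99, Mir337 1.85 ± 0.12, Mir7654 1.27 ± 0.55 and Mir182 1.25 ± 0.20 CPM on the opposite strand.

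A general loss of strand is argued against, since the median opposite-strand share of the 100 most abundant genes was 0% and 97 of them lay under 0.1%. A candidate explanation is that these rows stand opposite to a microRNA gene that has no row of its own: 99.8% of all opposite-strand counts lay in rows that overlap such a gene in GENCODE M21, and 14 of the 18 rows did. The 308 microRNA genes without a row all have an identifier above the highest in the tables. No biological explanation was tested, since the design gives a single group.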

How the results depend on the processing

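Alternatives named as added, and the removal of a trend with hairpin GC, were chosen after the data were seen. With 1 CPM in place of 10, 417 genes were detected, and with 100 CPM 186, a stricter bar by construction. The share of the 10 highest genes was 46.6% without Mir196b and 47.7% with counts of both strands. The correlation of the libraries was 0.992 with a pseudocount of 0.5 CPM, 0.997 with 10 CPM and 0.996 without a filter, all past its interval, and the cause was not tested. The coefficient of variation ranged from 15.9% to 16.4%. The binomial calls ranged from 168 to 182 over other scalings and minimums, and the negative binomial test gave 0. Leaving out rows with a gene on the other strand (added) took the opposite-strand share to 0.0043%. Without Mir196b, the Hox set, which lost it as a member, held 3.62%, while muscle held 0.271%, cartilage 2.81% and epithelium 2.06%, since the total shrank. With counts of both strands, cartilage held 2.5% and epithelium 1.83%, since the total grew. Other-strand counts of members without a row (added) raised white blood cells to 0.102%, the let-7 family to 5.29% and the Dlk1-Dio3 region to 6.03%. Without members that share a stretch, 15 of 20 set shares stayed within 1 SD and 5 did not: neural tissue at 0.0269%, pluripotent cells at 0.0143%, the Dlk1-Dio3 region at 3.75%, the Mir322-Mir503 region at 8.328% and the Mir297, Mir466, Mir467 and Mir669 families at 0.000011%. Of 18 differences between the libraries by set, all kept their side of the central 95% under other scalings and without the GC trend (added), and 17 did with members from 1 CPM, the exception being white blood cells. Without members matched by synonym (added) the let-7 family passed it. With counts of both strands 77 of 90 named genes stayed within 1 SD. Leaving out either replicate gave detection counts of 293 to 301 and shares of the 10 highest genes of 48.4% to 49.4%, and each kept the levels of all 90 named genes within 1 SD, which for 2 values is fixed by arithmetic. No paired analysis was possible because there is 1 group.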

Other observations

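The tests of copies, clusters and related hairpins and the choice of imprinted loci were made after values were seen. By place in the genome, microRNA genes in introns of protein-coding genes held 35.9% ± 0.92 of the counts, and those with no host gene on their own strand 22.1% ± 0.33. Exons of non-coding genes held 18.9% ± 0.12, and exons of protein-coding genes outside coding sequence and UTRs 15.5% ± 0.94. Genes on the other strand were not taken as hosts. A hairpin counted as exonic if it overlapped an exon of any annotated transcript of its host, so these shares depend on the annotated transcripts. Mir93 and Mir25 fell in exons of Mcm7, and their neighbour Mir106b in an intron. Chromosome 6, with Mir196b and Mir335, held 17.2% ± 1.56, and the X chromosome 10.9% ± 0.24. The 49 genes of imprinted loci (Dlk1-Dio3 with Mir335, Mir296, Mir298, Mir483 and Mir675) held 14.3% ± 0.35, of which the 5 genes outside Dlk1-Dio3 held 9.25% ± 0.33.

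Within single transcripts and clusters, levels spanned wide ranges. In the Mir17hg transcript, Mir17 stood at 50945 ± 7438 CPM and Mir20a at 17376 ± 2636, against 122 ± 4.8 CPM for Mir19a and 25.1 ± 1.8 for Mir19b-1, which shares a stretch with Mir19b-2. In the Mir106b cluster inside Mcm7, Mir93 (16019 ± 2327 CPM) and Mir106b (10448 ± 458 CPM) stood above Mir25 (829 ± 109 CPM).

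Genes with a copy elsewhere had low counts next to their neighbours. Beside Mir214, Mir199a-2 stood at 551 ± 141 CPM, and beside Mir99a (37341 ± 1902 CPM) Mirlet7c-1 stood at 56.7 ± 12.4 CPM. In 30 clusters on 1 strand with gaps of up to 10 kb that held both kinds, genes with a shared stretch lay below the others in 23, above them in 5 and tied at 0 counts in 2. Of the 28 without a tie, 82.1% were lower (two-sided exact sign test p = 0.000912), which is consistent with reads of identical copies left unassigned, as 23.7% to 27.2% of reads were set apart for mapping to several places. Low transcription of whole clusters is argued against as the whole source, since it lowers neighbours alike and the median log2 ratio of CPM plus 1 within the 30 clusters was -1.60 (95% interval -4.17 to -0.38). A part from it stays open. The test made first, the median of the neighbours (260 CPM, interval 4.71 to 2347), did not decide, and the bound of the ratio test was moved from -1 to 0 after its interval was seen. Separate promoters and uneven processing of neighbours were not tested.

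The spread between the libraries did not follow genomic clusters. In 25 clusters with 96 genes at 100 CPM or more, the intraclass correlation of log2 ratios was -0.025 (95% bootstrap interval -0.25 to 0.16, one-sided permutation p = 0.6), which argues against different transcription of whole clusters as the main source, and 6 of the clusters had members beyond a log2 ratio of 0.3 in both directions. A straight-line trend with hairpin GC is also argued against as the whole source. Spearman's rho with hairpin GC was 0.077 across 189 genes (interval -0.074 to 0.22, permutation p = 0.3). The SD of the ratios was 0.325 before and 0.323 after removal of this trend. GC bias of the reads themselves stays open, since the sequenced RNA is shorter than the hairpin and its GC was not measured. Recovery that depends on the microRNA sequence may contribute but stays open: in 20 pairs of related hairpins (15 nucleotides or more shared) from different clusters, of which 13 moved in the same direction about the mean, the correlation was 0.32 (interval -0.082 to 0.77, one-sided permutation p = 0.06), and -0.074 in the 12 pairs that share no stretch of 20 nucleotides with each other. A different tissue makeup of the pools stays open as well, with 1 of 11 tissue sets, red blood cells, outside the central 95%.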
